A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

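Total RNA of yeast cultures had been extracted with the Qiagen RNeasy kit and hybridised to 2-colour expression arrays, 6 for the mutator line m8 and 3 for the evolved non-mutator, each against the strain's own ancestor. The deposited values are linear ratios of the evolved strain (Cy5) over its ancestor (Cy3) on each array, where log ratios had been assumed in planning; channels are as the authors' labels give them, and the direction of the ratio is taken from them. Medians of the ratio were close to 1 on every array, which points to scaling within each array before deposition. The method of any such scaling, the background correction, the software and the signal intensities are not given in the sources used here, and no array had its dyes swapped.

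The arrays carried 6947 probes, of which 6377 bore a systematic gene name and 570 bore none. Names were matched to the R64 reference table of the species (5840 matched, 537 named probes did not), which was used for symbols, chromosomes and the order of neighbouring genes only, because the build of the array is not named. No gene had more than 1 probe. Missing values numbered 132 to 264 per mutator array and 20 to 24 per non-mutator array. The lowest ratio on every array was 0.01, found 35 to 132 times per mutator array and 2 to 4 times per non-mutator array, and was treated as a floor (to a tolerance of 1e-04) and set to missing. Ratios with no more than 1 decimal, to the same tolerance, numbered 105 to 198 per mutator array and 2 to 5 per non-mutator array and were kept. The array sets differed in these counts for a reason the labels do not give.

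Ratios were turned into log2 ratios and centred on the median of each array. The repeat mutator arrays carry the evolved RNA numbers 1, 2 and 3 of the first round (the repeat of number 2 was set against ancestor RNA number 1), so both arrays of a number were averaged to 1 replicate. The non-mutator arrays were taken as replicates 2, 3 and 4 by their titles, although their descriptions carry other numbers. Averaging mixes both rounds in each replicate of the 6173 tested probes with a value on all 6 mutator arrays; in the other 693 some replicates rest on 1 array or have no value, and 53 of these had values from 1 round only. Measured from the mean of all 6 mutator arrays, same-number arrays of the rounds deviated in opposite directions (r = -0.435, -0.493 and -0.357 across probes for numbers 1, 2 and 3). The difference between rounds stays in these deviations, so r below 0 does not show by itself that same-number arrays disagree. The consensus correlation was -0.314 within RNA numbers and 0.297 within rounds.

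Probes with a value in at least 2 replicates of each group were tested (6866 of them, 81 not). A linear model with a mean per group and 4 residual degrees of freedom was fitted in limma 3.58.1 (lmFit and eBayes, R 4.3.3), and each group mean and the difference of the means (mutator minus non-mutator) were tested two-sided against 0. Calls used a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Gene lists and chromosomes with at least 5 tested genes were tested with camera (preset correlation 0.01), adjusted over the 42 lists or over the chromosomes, with camera at an estimated correlation and fry beside it. The members of each list were also adjusted over the list alone. IMD1, PIS1 and TPO3 matched no probe. Overlap of calls was tested with Fisher's exact test, two-sided, adjusted over the 4 directions.

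The lists covered DNA repair (mismatch, base excision, nucleotide excision, homologous recombination, translesion), replication, dNTP supply, stress, carbon and energy metabolism, translation, mating and cell type, cell wall, biosynthesis, metals, phosphate, lipids, chromatin, cell cycle, protein turnover, transport and markers. Genes were named by rule: the 10 highest and the 10 lowest per comparison among those called (with the same sign in every replicate, for each evolved strain against its ancestor), up to 4 members with the smallest p of each list with a shift or a member that passed, and the mismatch repair genes, of which some are not reported here. Other genes are identified as chosen after their values were seen. Comparisons, lists, naming rule and most alternatives were chosen before the data were examined; 4 alternatives and 4 further lists were added later.

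Alternatives run were no centring, arrays scaled to the same median absolute deviation, the 6 mutator arrays as replicates or with the RNA number as a random block, either round alone, each group fitted alone, robust eBayes, array weights, stricter and looser filters on missing values, thresholds of adjusted p under 0.01 or a log2 size of at least 1, rank-based camera, a replicate block and leaving out each replicate. The alternatives added later were floor ratios kept, ratios with no more than 1 decimal set to missing, only probes of reference genes, and the hybridisation round as a random block. For the random blocks, robust eBayes and array weights, lists and chromosomes were tested with cameraPR, which runs camera on the t-values of the fit. A list call lost or gained there may come from the setting or from this change of test. The procedure was tested on simulated data of 6866 probes with 200 changed genes per group. Recovery at log2 sizes of 0.25, 0.5, 1 and 2 was 32%, 70%, 90% and 92% for the mutator, 26%, 72%, 94% and 94% for the non-mutator and 16.5%, 57%, 85.9% and 89.8% for the difference. False calls made up 5.33%, 6.54% and 5.02% of calls. In the simulated mutator 0 of 42 lists passed with no shift, and with 1 list shifted that list and 1 other passed. Simulated noise was independent between probes, with no correlation among genes and no difference between rounds. Each probe had the same replicate spread in both groups, and far fewer genes changed than the 5154 probes called in the mutator. Simulated values entered the fit as log2 ratios, so centring and the treatment of the floor were not tested. The simulation therefore cannot show how the list test or the share of false calls behaves where genes are correlated or rounds differ. Nor can it show this where the groups differ in spread or most genes change.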

Results

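Gene expression was compared in the budding yeast Saccharomyces cerevisiae between strains evolved for 6700 generations and the strains they came from. On 6 arrays the evolved strain was m8, one of the mutator lines, that is, a line whose ancestor already had a raised mutation rate, and the reference RNA on the array was that of the mutator ancestor. On 3 arrays, the control of the design, an evolved non-mutator strain was set against its own non-mutator ancestor. Cells had been grown in YPD, a rich medium, in 3 ml in glass tubes to an OD600 of about 0.3. The 6 mutator arrays made up 3 replicates, because a first round of 3 hybridisations was followed by a repeat round carrying the same evolved RNA numbers, and both arrays of a number were averaged. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

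Values are log2 ratios of the evolved strain over its ancestor, centred on the median of each array, and given as mean ± SD over replicates. Evolved over ancestor is the likely direction, since the labels put the evolved strain in Cy5 and the ancestor in Cy3 on every array, but the direction is not stated with the values. The median deposited ratio was 1.07, 1.07 and 1.06 on first-round mutator arrays 1, 2 and 3, 1.06, 1.07 and 1.06 on their repeats, and 1.01, 1.0 and 1.0 on non-mutator arrays 2, 3 and 4. Centring therefore lowered mutator log2 ratios by 0.10 on average. The SD of log2 ratios across probes was 0.85 to 1.0 on mutator arrays and 0.28 to 0.30 on non-mutator arrays. Across probes, Pearson's r between arrays was 0.845 to 0.949 within the first mutator round, 0.810 to 0.843 within the repeat round, 0.729 to 0.881 among non-mutator arrays and -0.0319 to 0.0574 between the array sets. From one mutator round to the other, r was 0.749 to 0.835 for the same RNA number and 0.751 to 0.847 for different numbers. Arrays averaged to 1 replicate were thus no more alike than arrays of different numbers.

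The first comparison asked how expression in the mutator line differed from that of its ancestor after evolution. The tryptophan synthase gene TRP5 (YGL026C) rose by 6.68 ± 0.63 (SD, n = 3), which is 102-fold (limma, adjusted p = 1.5e-06). URA3 (YEL021W), which encodes the last enzyme of uridylate synthesis, rose by 4.17 ± 1.12 (SD, n = 3), with an adjusted p of 9.4e-05. The meiotic spindle pole body gene SPO21 (YOL091W) fell to -5.89 ± 0.08 (SD, n = 3) and EGO4 (YNR034W-A) to -5.95 ± 0.10 (SD, n = 3), 59.2-fold and at least 62-fold lower (adjusted p = 1.1e-07 and 1.5e-07). The histidine synthesis gene HIS3 (YOR202W) fell to -4.87 ± 0.06 (SD, n = 3), and the small heat shock protein gene HSP26 to -5.62 ± 0.22 (SD, n = 3). The other genes with the largest increases were the mitochondrial oxaloacetate carrier gene OAC1 (3.90 ± 0.14), the condensin gene BRN1 (3.24 ± 0.09), the bud site selection gene BUD5 (3.21 ± 0.77), the RNA-binding protein gene PUF3 (3.15 ± 0.25) and the leucine synthesis gene LEU1 (3.11 ± 0.04). They also included the heme synthesis gene HEM3 (2.75 ± 0.09), the ribosome assembly gene RSA4 (2.61 ± 0.05) and YGR160W (2.46 ± 0.52). Of the probes tested, with floor ratios set to missing, the other genes with the largest decreases were RGI1 (-4.74 ± 0.07), the glycogen phosphorylase gene GPH1 (-4.70 ± 0.30), YRO2 (-4.59 ± 0.22) and the hexokinase gene HXK1 (-4.52 ± 0.17). The mating-type regulator genes HMLALPHA1 (-5.08 ± 0.37) and MATALPHA1 (-5.08 ± 0.47) are near-identical copies, so which of them changed is uncertain. RGI1 and YRO2 differed between hybridisation rounds: RGI1 was -5.78 in the first round and -3.69 in the repeat, and YRO2 -3.50 in the first round and -5.68 in the repeat. In all, 5154 of 6866 probes passed, 2561 higher and 2593 lower. The even split depended on centring, without which 3011 of 5217 were higher. Changes of at least 2-fold numbered 1241 (492 higher, 749 lower), and of at least 4-fold 222 (33 higher, 189 lower). For the 6173 probes with a value on all 6 mutator arrays, each replicate averages 1 first-round and 1 repeat array, so differences between rounds cancel within it and these p-values leave them out. For the other 693 they can enter the mean and SD. EGO4 had 1 value above the floor in the first round (-6.48, against -5.82 in the repeat), and HMLALPHA1 1 such value in the repeat (-4.05, against -5.34 in the first round). As ratios at the floor were set to missing, the decreases of both are lower bounds. With the round as a random block 4161 probes passed.

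Of 42 gene lists, 19 shifted in the mutator, 8 up and 11 down, relative to the other genes (camera, preset correlation), and 0 passed with an estimated correlation (lowest adjusted p = 0.14). The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, passed 40 lists in the mutator, 16 in the non-mutator and 38 in the difference. Some lists share genes, such as HSP26 and HSP104 (general stress and heat shock chaperones) or POL1 (replicative polymerases and G1 and S phase). Their shifts are therefore not independent of each other. Medians of lists are given ± SD of the replicate medians (n = 3). Genes for making ribosomes rose: 61 of 61 ribosome biogenesis genes passed, all higher, with a median of 1.39 ± 0.03 (adjusted p = 8.6e-19, and adjusted p = 0.15 with an estimated correlation). Among them were NOG1 (2.16), RPF2 (2.03), UTP8 (1.76) and HAS1 (1.45). Of 138 cytosolic ribosomal protein genes, 131 rose and 0 fell (median 0.44 ± 0.09, adjusted p = 4.2e-14, and adjusted p = 0.29 with an estimated correlation), for example RPS28B (1.02), RPL15A (0.96) and RPL22A (0.93). Of 32 translation factor genes, 24 rose and 1 fell, with a median of 0.40 ± 0.01 (adjusted p = 0.00018, and adjusted p = 0.15 with an estimated correlation), for example the initiation factor genes PRT1 (1.29), GCD2 (1.10) and TIF5 (1.03). Genes periodic in G1 and S phase rose in 24 of 28 cases and 1 fell (median 0.66 ± 0.04, adjusted p = 3.0e-05, and adjusted p = 0.14 with an estimated correlation). They included the ribonucleotide reductase gene RNR1 (1.69), the cyclin gene CLB6 (1.53) and the replication licensing gene CDC6 (1.24). Of 23 G2 and M phase genes, 19 rose and 2 fell (median 0.58 ± 0.03, adjusted p = 0.00042, and adjusted p = 0.16 with an estimated correlation), with the polo kinase gene CDC5 at 1.30 and the cyclin gene CLB2 at 1.18. The replicative DNA polymerase list had 10 of 11 genes higher and 0 lower (median 0.62 ± 0.10, adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation), among them POL1 (1.14), POL3 (0.99) and POL32 (0.71). In pyrimidine synthesis 10 of 13 genes rose and 2 fell (median 0.72 ± 0.03, adjusted p = 0.027, and adjusted p = 0.19 with an estimated correlation). The CTP synthase gene URA7 (1.51) and the dihydroorotate dehydrogenase gene URA1 (1.09) rose, while URA8 (-1.83), a paralogue of URA7, and URA10 (-2.44) fell. Counts adjusted over the list alone were identical in these lists.

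Stress genes fell furthest as a list. Of 32 general stress response genes, 31 fell and 0 rose (0 rose and 32 fell adjusted over the list alone), with a median of -2.90 ± 0.08 (adjusted p = 1.3e-13, and adjusted p = 0.15 with an estimated correlation). Examples were the glucokinase gene GLK1 (-3.94), the trehalose synthase subunit gene TSL1 (-3.91), the glutamate decarboxylase gene GAD1 (-3.89) and the aldehyde dehydrogenase gene ALD3 (-3.30). Of 28 heat shock chaperone genes, 21 fell and 2 rose (median -0.42 ± 0.07, adjusted p = 0.00053, and adjusted p = 0.19 with an estimated correlation), with HSP30 (-4.27), HSP104 (-3.04) and SSE2 (-2.68) the examples after HSP26. Of 23 oxidative stress defence genes, 19 fell and 1 rose (median -0.65 ± 0.0032, adjusted p = 0.00014, and adjusted p = 0.14 with an estimated correlation), among them the peroxidase genes TSA2 (-2.89), GPX1 (-2.07) and PRX1 (-1.80). Of 20 genes of glycolysis and fermentation, 17 fell and 0 rose (median -0.48 ± 0.05, adjusted p = 0.00014, and adjusted p = 0.19 with an estimated correlation), such as PYK2 (-3.53), TDH1 (-1.18) and PGK1 (-0.86). In the tricarboxylic acid cycle 11 of 12 genes fell and 0 rose (median -0.54 ± 0.09, adjusted p = 0.0020, and adjusted p = 0.15 with an estimated correlation), including CIT1 (-1.16), MDH1 (-1.01) and KGD2 (-0.74). Of 35 oxidative phosphorylation genes, 26 fell and 1 rose (median -0.28 ± 0.03, adjusted p = 0.00055, and adjusted p = 0.29 with an estimated correlation), for example the succinate dehydrogenase genes SDH4 (-1.66), SDH2 (-1.42) and SDH1 (-1.07), but on the repeat arrays alone the median was 0.08. In the phosphate regulon 17 of 21 genes fell and 2 rose (median -1.34 ± 0.10, adjusted p = 0.00014, and adjusted p = 0.14 with an estimated correlation). The phosphate transporter gene PHO84 was at -2.38 and the nucleotide phosphatase gene PHM8 at -3.12, and the near-identical acid phosphatase genes PHO11 (-3.59) and PHO12 (-3.52) cannot be read separately. Of 26 mating pheromone response genes, 16 fell and 1 rose (median -0.75 ± 0.19, adjusted p = 0.0016, and adjusted p = 0.19 with an estimated correlation), among them the a-factor genes MFA1 (-4.0) and MFA2 (-2.11), the cell fusion gene FUS1 (-2.72) and the agglutinin gene AGA2 (-2.23). Of 32 proteasome genes, 25 fell and 1 rose (1 rose and 26 fell adjusted over the list alone), with a median of -0.34 ± 0.02 (adjusted p = 0.00072, and adjusted p = 0.15 with an estimated correlation), for example PRE1 (-0.55), SCL1 (-0.55) and RPT2 (-0.49). Of 32 cell wall genes, 21 fell and 7 rose (median -0.39 ± 0.05, adjusted p = 0.0092, and adjusted p = 0.33 with an estimated correlation), with PIR3 (-3.76), CHS1 (-1.71) and YPS1 (-1.70) the examples. Of 30 genes repressed by good nitrogen sources, 18 fell and 6 rose (median -0.57 ± 0.03, adjusted p = 0.017, and adjusted p = 0.16 with an estimated correlation). The ammonium permease gene MEP2 (-2.55) and the amino acid permease gene GAP1 (-1.52) fell, while the ornithine transaminase gene CAR2 (1.79) rose, and ASP3-2 (-1.23) is 1 of several near-identical copies. Besides the estimated correlation, alternatives lost the calls of the proteasome (4), pyrimidine synthesis (4), oxidative phosphorylation (2) and the tricarboxylic acid cycle (1), with the number of such alternatives in brackets. Not counted there, oxidative phosphorylation also lost its call on repeat arrays only, where its median reversed (camera, adjusted p = 0.74). In lists without a second count, that adjusted over the list alone was identical.

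Mismatch repair was looked at separately because the series concerns mutation rates. Of 14 genes of the list, 10 rose and 2 fell in the mutator, the same counts adjusted over the list alone (median 0.46 ± 0.06, adjusted p = 0.030, and adjusted p = 0.19 with an estimated correlation). The mismatch recognition gene MSH6 rose by 1.13 ± 0.14 (SD, n = 3), the sliding clamp gene POL30 by 0.98 ± 0.06, the clamp loader gene RFC1 by 0.91 ± 0.09 and the exonuclease gene EXO1 by 0.57 ± 0.01. MSH3 stood at 1.51 ± 1.08 (adjusted p = 0.0093) on first-round arrays alone, as no repeat array gave a value for it. PMS1 stood at 0.56 ± 0.20 and the clamp loader genes RFC3, RFC4 and RFC5 at 0.28 ± 0.07, 0.61 ± 0.15 and 0.35 ± 0.07. MLH3 fell to -0.49 ± 0.12, and RFC2 (0.07 ± 0.06) was among the genes that did not pass. RFC3 reached only 0.07 on the repeat array of replicate 3. Sliding clamp and clamp loader genes thus make up part of the list and of its increases. The lists of replicative DNA polymerases and of G1 and S phase genes rose in the mutator too. Whether the shift is particular to mismatch repair was not tested. In the non-mutator 1 of the 14 genes passed, RFC5 at 0.17 ± 0.05, and 0 adjusted over the list alone. The list's call in the mutator was also lost with the RNA number or the round as a random block, robust eBayes or array weights. These fits used cameraPR for lists, so the setting and the change of test cannot be told apart. The call of RFC5 in the non-mutator was lost in 10 of 21 alternatives. The list's shift did not pass the test of the difference between mutator and non-mutator (median difference 0.41, adjusted p = 0.073), though the differences of MSH6 (1.01), POL30 (1.0) and RFC1 (1.02) did.

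Other repair lists did not shift as lists in the mutator. They were base excision repair (3 rose and 7 fell of 10, adjusted p = 0.22), nucleotide excision repair (7 rose and 5 fell of 16, adjusted p = 0.99) and homologous recombination (7 rose and 4 fell of 17, adjusted p = 0.47). They were also translesion synthesis and postreplication repair (5 rose and 2 fell of 10, adjusted p = 0.52) and dNTP synthesis and DNA damage checkpoint (10 rose and 8 fell of 19, adjusted p = 0.75). Single members passed in both directions: the alkyladenine glycosylase gene MAG1 (-1.60) and the photolyase gene PHR1 (-1.49) fell, while the oxoguanine glycosylase gene OGG1 (1.33) and the translesion polymerase gene REV1 (0.97) rose. Among lists of metabolism, thiamine and pyridoxine synthesis (3 rose and 14 fell of 23, adjusted p = 0.053), glucose-repressed carbon metabolism (3 rose and 13 fell of 21, adjusted p = 0.054) and amino acid biosynthesis (18 rose and 36 fell of 61, adjusted p = 0.064) did not pass. Nor did sulfur and methionine metabolism (5 rose and 17 fell of 27, adjusted p = 0.075), ergosterol synthesis (4 rose and 15 fell of 26, adjusted p = 0.10), purine and one-carbon metabolism (11 rose and 9 fell of 23, adjusted p = 0.73) or phospholipid synthesis (7 rose and 6 fell of 21, adjusted p = 0.99). In amino acid synthesis LEU1 and the transaminase gene BAT1 (1.92) rose, and HIS3 and ARG4 (-2.95) fell. Of transport and metal lists, hexose transport (4 rose and 7 fell of 15, adjusted p = 0.20), multidrug resistance (8 rose and 5 fell of 17, adjusted p = 0.76) and copper and zinc homeostasis (8 rose and 4 fell of 17, adjusted p = 0.44) did not pass. Within them the glucose transporter gene HXT4 (-2.98) and the copper transporter gene CTR1 (-1.99) fell, and the drug efflux gene PDR5 (1.36) rose. The list iron regulon (12 rose and 10 fell of 27, adjusted p = 0.66) had a median of -0.11 ± 0.11 but a mean of 0.12, and its median was 0.48 on the repeat arrays alone, where it passed as higher (adjusted p = 0.013). Of lists on cell type and structure, haploid-specific genes (3 rose and 8 fell of 15, adjusted p = 0.17), meiosis and sporulation (9 rose and 12 fell of 33, adjusted p = 0.66) and histones (6 rose and 0 fell of 10, adjusted p = 0.053) did not pass. The same held for daughter-cell separation (2 rose and 10 fell of 15, adjusted p = 0.12), flocculins and cell-surface adhesion (2 rose and 7 fell of 12, adjusted p = 0.21), telomere maintenance and silencing (12 rose and 6 fell of 23, adjusted p = 0.24) and auxotrophic marker genes (3 rose and 7 fell of 10, adjusted p = 0.062). Examples were the chitinase gene CTS1 (-2.02) and the meiotic repressor gene RME1 (-1.53), which fell, and the silencing gene SIR2 (1.13), which rose. Some of these lists passed in alternatives, whose number follows in brackets: auxotrophic marker genes (9), histones (8), thiamine and pyridoxine synthesis (7), glucose-repressed carbon metabolism (6), hexose transport (6), amino acid biosynthesis (3), daughter-cell separation (1), ergosterol synthesis (1), flocculins and cell-surface adhesion (1) and sulfur and methionine metabolism (1). Adjusted over the list alone, no count of these 23 lists moved by more than 1.

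Several of the genes with extreme ratios are ones that laboratory yeast strains often carry as markers. Of the 10 marker genes of that list, HIS3, TRP1 (-2.71 ± 0.15), MET17 (-2.10 ± 0.13), HIS4 (-2.72 ± 0.26) and the purine synthesis gene ADE2 (-2.83 ± 0.36) fell at least 4-fold in the mutator, and URA3 rose at least 4-fold. Of these genes past 4-fold, HIS3 rose in the non-mutator and the others did not pass, ADE2 being nearest at 0.46 ± 0.09 (adjusted p = 0.051). LEU2, also on the marker list, fell in the non-mutator (-0.87, limma, adjusted p = 0.00057). Neighbours of the genes past 4-fold, taken from the R64 reference table by gene order only, moved less on the whole. The median of the 4 genes on either side was -0.65 around MET17, 0.08 around TRP1, -0.06 around HIS4, 0.24 around HIS3, 0.10 around URA3, -0.37 around ADE2 and 0.09 around TRP5. Single neighbours moved as far, such as FUS1 (-2.72 ± 0.24) near HIS4. BUD5 and MATALPHA1 lie on either side of MATALPHA2 (-0.16 ± 0.09), and beyond MATALPHA1 come YCR041W (-3.18 ± 0.88) and TAF2 (-1.92 ± 0.13). ADE2, MATALPHA2, YCR041W and TAF2 were chosen after their values were seen.

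**Figure D1:**
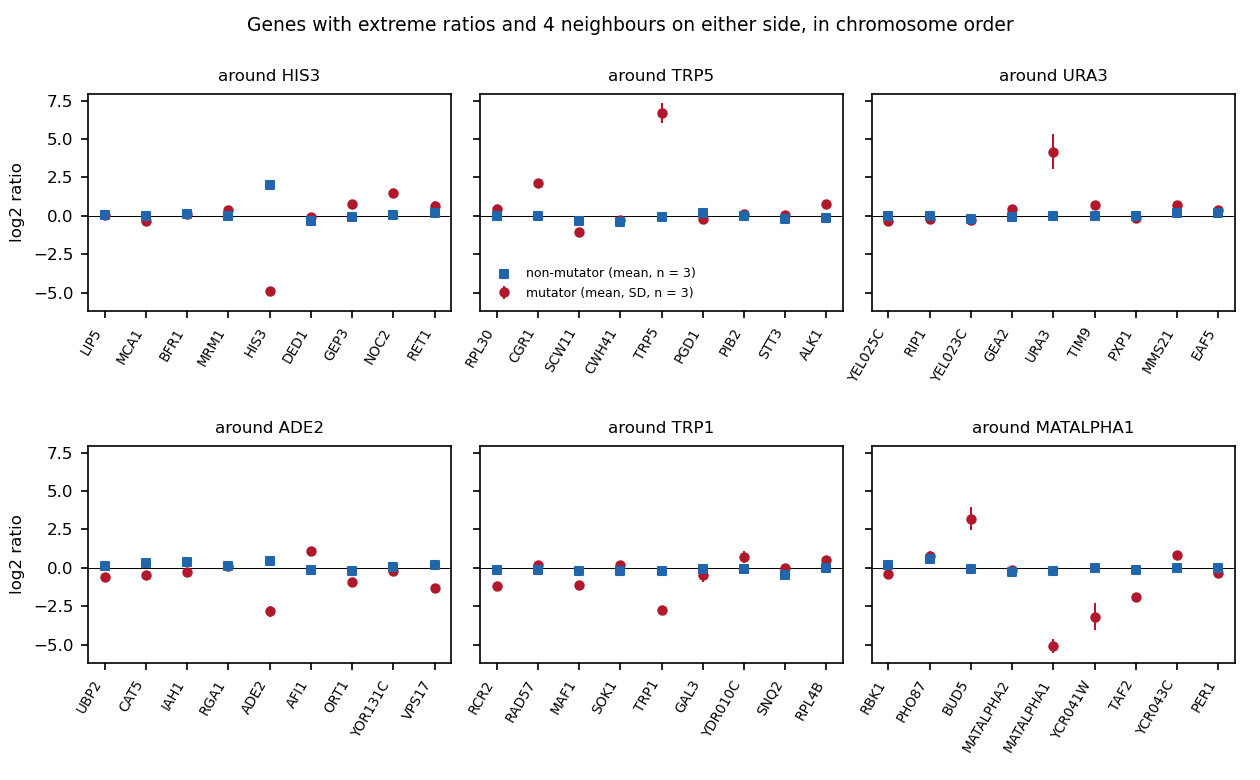
Mean log2 ratio (evolved over ancestor) of 6 genes with extreme ratios and the 4 genes on either side of each, in chromosome order; circles with SD bars are the mutator (n = 3) and squares the non-mutator. HIS3 stands at -4.87 in the mutator and 2.01 in the non-mutator, while the neighbours of HIS3 lie between -0.33 and 1.5 in the mutator.

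The rounds of mutator arrays were compared with each other, since the repeat round is a batch within that group. The high-affinity iron permease gene FTR1 was 0.07 in the first round and 1.44 in the repeat (adjusted p = 0.0020), and the ferroxidase gene FET3 was -0.17 in the first round and 1.38 in the repeat (adjusted p = 0.0021). The cyclin gene CLB6 was 2.05 in the first round and 1.0 in the repeat, the respiratory dehydrogenase gene NDI1 -2.12 in the first round and -1.13 in the repeat, and the chaperone gene HSP104 -3.54 in the first round and -2.53 in the repeat. Other genes named here that differed, with the first round before the repeat, were STE2 (-0.68 and -1.43), RNR1 (1.99 and 1.38), GPX1 (-2.43 and -1.71), HAS1 (1.72 and 1.19), CDC5 (1.69 and 0.91), HSP30 (-3.77 and -4.77), GAP1 (-1.04 and -1.99), PGM2 (-4.61 and -3.82), SER3 (0.72 and -0.32), ENB1 (-1.13 and 0.03) and ZRT1 (0.77 and -0.45). Of 6173 probes with enough values, 350 differed, 212 higher and 138 lower in the repeat. Of the lists, 13 differed with the preset correlation and none with an estimated one (lowest adjusted p = 0.13 with an estimated correlation). First-round and repeat medians were -3.31 and -2.60 for general stress, -0.63 and 0.08 for oxidative phosphorylation, -0.18 and 0.45 for the iron regulon and 1.42 and 1.41 for ribosome biogenesis. Other lists shifted in the mutator also differed between rounds. In the same order, medians were -0.71 and -0.33 for heat shock chaperones and -0.79 and -0.50 for oxidative stress defence. They were -0.72 and -0.33 for the tricarboxylic acid cycle and -0.41 and -0.26 for the proteasome. For G1 and S phase they were 0.83 and 0.59, and for G2 and M phase 0.77 and 0.50. Pearson's r of the round means across probes, which are not independent replicates, was 0.847.

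The second comparison, of the evolved non-mutator with its ancestor, is the control of the design for evolution without a raised mutation rate. It covers a single evolved strain, as the first comparison covers the single line m8. A difference between them therefore cannot be assigned to the mutation rate rather than to the line or its ancestor. The a-factor gene MFA1 (YDR461W) was at -2.81 ± 0.09 (SD, n = 3), or 7.01-fold lower (limma, adjusted p = 0.00017), MFA2 at -2.39 ± 0.12, the barrier protease gene BAR1 at -2.49 ± 0.51 and the alpha-factor receptor gene STE2 at -2.07 ± 0.09. FET3 (YMR058W) fell to -2.78 ± 0.22 (SD, n = 3), with an adjusted p of 6.4e-05. Phosphate genes fell as well, namely SPL2 (-2.18 ± 0.17), the phosphate transporter gene PHO89 (-1.95 ± 0.23) and the near-identical pair PHO11 (-1.97 ± 0.09) and PHO12 (-1.93 ± 0.08). YNL089C fell to -1.96 ± 0.85. Of the probes tested HIS3 rose most, by 2.01 ± 0.05 (SD, n = 3), or 4.02-fold (adjusted p = 2.5e-05). The vacuolar mannosidase gene AMS1 (1.21 ± 0.07), the oxidative folding gene ERO1 (1.06 ± 0.12), the protein degradation gene DER1 (1.04 ± 0.08), the autophagy gene ATG17 (1.05 ± 0.12) and the glutathione transferase gene GTT1 (1.04 ± 0.05) rose too. Increases were also seen for YGL258W-A (1.37 ± 0.05), ULI1 (1.09 ± 0.08), YPS5 (1.12 ± 0.12) and YPS6 (1.07 ± 0.06). Alternatives lost the calls of YGL258W-A (5), YNL089C (2) and YPS6 (1), with their number in brackets. In all, 1457 of 6866 probes passed, 698 higher and 759 lower. Changes of at least 2-fold numbered 49 (15 higher, 34 lower), and of at least 4-fold 7 (1 higher, 6 lower). The total rests on each array: 603, 347 and 351 probes passed without non-mutator replicate 2, 3 and 4. It also rests on the fit, with 83 probes where the hybridisation round was a random block, which holds these 3 arrays in 1 block, and 3455 where arrays were scaled to the same spread.

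In the non-mutator 11 of the 42 lists shifted, 1 up and 10 down, and 0 passed with an estimated correlation. In the phosphate regulon 14 of 21 genes fell and 1 rose (2 rose and 17 fell adjusted over the list alone), with a median of -0.96 ± 0.05 (adjusted p = 1.4e-10, and adjusted p = 0.066 with an estimated correlation), and the alkaline phosphatase gene PHO8 was at -1.30. Of 26 mating pheromone response genes, 13 fell and 0 rose, the same adjusted over the list alone (median -0.30 ± 0.06, adjusted p = 1.2e-08, and adjusted p = 0.16 with an estimated correlation). The a-factor exporter gene STE6 was at -1.65. Of 15 haploid-specific genes, 5 fell and 1 rose (1 rose and 6 fell adjusted over the list alone), with a median of -0.11 ± 0.07 (adjusted p = 0.036, and adjusted p = 0.30 with an estimated correlation). Among them were the pheromone signalling genes SST2 (-1.82), FAR1 (-1.13) and GPA1 (-0.81). Of 61 amino acid synthesis genes, 24 fell and 1 rose (2 rose and 29 fell adjusted over the list alone), with a median of -0.16 ± 0.01 (adjusted p = 2.3e-07, and adjusted p = 0.083 with an estimated correlation), such as SER3 (-1.23), LEU1 (-0.96) and LEU2 (-0.87). Of 26 ergosterol synthesis genes, 15 fell and 1 rose (2 rose and 17 fell adjusted over the list alone), with a median of -0.26 ± 0.04 (adjusted p = 6.3e-06, and adjusted p = 0.17 with an estimated correlation), for example ERG3 (-0.81), MVD1 (-0.60) and ERG11 (-0.54). Of 32 proteasome genes, 9 fell and 0 rose (0 rose and 14 fell adjusted over the list alone), with a median of -0.13 ± 0.01 (adjusted p = 4.3e-05, and adjusted p = 0.16 with an estimated correlation), for example PRE9 (-0.30) and RPT1 (-0.30). Of 27 iron regulon genes, 10 fell and 0 rose, unchanged adjusted over the list alone (median -0.19 ± 0.05, adjusted p = 0.00093, and adjusted p = 0.20 with an estimated correlation). The siderophore transporter gene ENB1 was at -0.66 and FTR1 at -0.45. Of 23 purine and one-carbon genes, 7 fell and 1 rose (2 rose and 8 fell adjusted over the list alone), with a median of -0.13 ± 0.04 (adjusted p = 0.0088, and adjusted p = 0.52 with an estimated correlation), such as the glycine cleavage gene GCV1 (-0.73) and ADE12 (-0.45). Of 15 daughter-cell separation genes, 7 fell and 2 rose (2 rose and 8 fell adjusted over the list alone), with a median of -0.31 ± 0.04 (adjusted p = 0.0088, and adjusted p = 0.33 with an estimated correlation), including DSE4 (-0.54) and NIS1 (-0.52). Of 17 copper and zinc genes, 6 fell and 0 rose (0 rose and 7 fell adjusted over the list alone), with a median of -0.08 ± 0.07 (adjusted p = 0.030, and adjusted p = 0.33 with an estimated correlation), such as COT1 (-0.51), ADH4 (-0.46) and ZRT1 (-0.29). Of the genes named here, alternatives lost the calls of EBP2 and RPT1 (7 each), NOG1 (6), ADH4, RPF2 and ZRT1 (5 each), ENB1, FTR1 and PRE9 (3 each), COT1 (2) and DSE4, MVD1, NIS1 and SER3 (1 each). Besides the estimated correlation, 6 alternatives lost the call of haploid-specific genes and 5 that of copper and zinc genes. The list that rose was ribosome biogenesis, with 12 of 61 genes higher and 0 lower, unchanged adjusted over the list alone (median 0.11 ± 0.04, adjusted p = 0.00032, and adjusted p = 0.58 with an estimated correlation), for example EBP2 (0.49), RPF2 (0.33) and NOG1 (0.31).

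Among the 31 lists that did not pass in the non-mutator, general stress had 6 genes higher and 2 lower of 32 (median 0.03 ± 0.01, adjusted p = 0.45), with GPH1 (0.73) and PGM2 (0.63) higher and ALD3 (-0.50) lower. Cytosolic ribosomal proteins had 2 of 138 genes higher (median 0.02 ± 0.04, adjusted p = 0.12), and 0 adjusted over the list alone. Translation factors had 0 higher and 0 lower of 32. The lists nearest to passing were phospholipid synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, multidrug resistance, thiamine and pyridoxine synthesis, cell wall, glucose-repressed carbon metabolism, tricarboxylic acid cycle, glycolysis and fermentation, general stress response and histones (adjusted p = 0.076 to 0.45). Next came base excision repair, nucleotide excision repair, replicative DNA polymerases, homologous recombination, dNTP synthesis and DNA damage checkpoint, hexose transport, sulfur and methionine metabolism, G2 and M phase cell cycle, mismatch repair, flocculins and cell-surface adhesion and nitrogen catabolite repressed (adjusted p = 0.53 to 0.88). The remaining lists were pyrimidine synthesis, telomere maintenance and silencing, translesion synthesis and postreplication repair, oxidative stress defence, translation factors, meiosis and sporulation, G1 and S phase cell cycle, heat shock chaperones and auxotrophic marker genes (adjusted p = 0.88 to 0.92). In 1 alternative each, cytosolic ribosomal proteins, oxidative phosphorylation, phospholipid synthesis and thiamine and pyridoxine synthesis passed. Adjusted over the list alone, no count of these lists moved by more than 3.

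**Figure D2:**
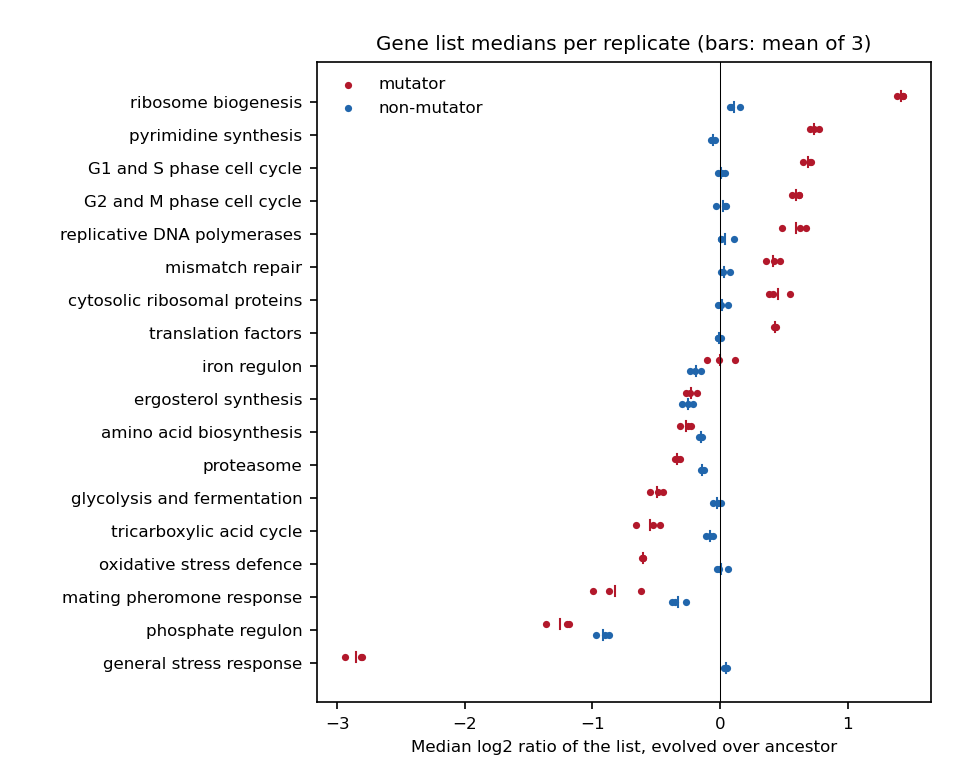
Median log2 ratio (evolved over ancestor) of 18 gene lists in each replicate; each point is 1 replicate, bars are the means of 3 replicates, red is the mutator and blue the non-mutator. General stress response lies near -2.90 in the mutator and 0.03 in the non-mutator, and the phosphate regulon at -1.34 and -0.96.

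The third comparison asked which changes differed between mutator and non-mutator, and is given as mutator minus non-mutator. Of the probes tested, with floor ratios set to missing, HIS3 differed most, by -6.88 (SE 0.07), being -4.87 in the mutator and 2.01 in the non-mutator (limma, adjusted p = 1.8e-07). TRP5 differed by 6.75 (SE 0.30), against -0.07 in the non-mutator, where it did not pass (adjusted p of the difference 1.0e-05). OAC1 (4.70, SE 0.09) and LEU1 (4.07, SE 0.06) rose in the mutator and fell in the non-mutator, to -0.79 and -0.96. FET3 differed by 3.39 (SE 0.12), being 0.61 in the mutator, where its rounds disagreed, and -2.78 in the non-mutator. The other largest positive differences were URA3 (4.21), BUD5 (3.28), PUF3 (2.97), HEM3 (2.91), BRN1 (2.76) and RSA4 (2.54). The other largest negative ones were EGO4 (-6.64), SPO21 (-5.77), HSP26 (-5.72), GPH1 (-5.43), RGI1 (-5.09), YRO2 (-5.05) and RTC2 (-4.97), and HMLALPHA1 (-4.96) and MATALPHA1 (-4.90), read as 1 signal. The values of EGO4 and HMLALPHA1 are lower bounds in size, and with floor ratios kept EGO4 differed more than HIS3. In all, 4390 of 6866 probes differed, 2266 higher and 2124 lower in the mutator, 1328 of them by at least 2-fold (507 higher, 821 lower). Without centring 2707 of 4608 were higher. With the hybridisation round as a random block 2675 differed. The array sets also differ in their spread and missing values, so array set and strain cannot be told apart in this comparison. With a single evolved line on each side, mutation rate cannot be told apart from the line either.

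Of the 42 lists, 14 differed between mutator and non-mutator, 7 higher and 7 lower in the mutator, and 0 with an estimated correlation. Ribosome biogenesis was higher, with 60 of 61 genes higher and 0 lower (median difference 1.33, adjusted p = 7.1e-18, and adjusted p = 0.19 with an estimated correlation), for example UTP8 (1.77), HAS1 (1.42) and IMP3 (1.51). General stress was lower, with 31 of 32 genes lower and 0 higher (median difference -2.93, adjusted p = 3.1e-15, and adjusted p = 0.16 with an estimated correlation), such as PGM2 (-4.84), GAD1 (-4.27) and TSL1 (-3.66). Of 138 cytosolic ribosomal protein genes, 106 were higher and 0 lower, against 111 and 0 adjusted over the list alone (median difference 0.39, adjusted p = 8.8e-11, and adjusted p = 0.42 with an estimated correlation). Median differences above 0 were also found for translation factors (0.42, adjusted p = 0.00053, and adjusted p = 0.19 with an estimated correlation) and for G1 and S phase (0.65, adjusted p = 0.00018, and adjusted p = 0.16 with an estimated correlation). The same was found for G2 and M phase (0.61, adjusted p = 0.0031, and adjusted p = 0.27 with an estimated correlation) and the replicative DNA polymerases (0.59, adjusted p = 0.016, and adjusted p = 0.24 with an estimated correlation), and for pyrimidine synthesis (0.84, adjusted p = 0.028, and adjusted p = 0.24 with an estimated correlation). Examples were RNR1 (1.90), CLB6 (1.54), CDC5 (1.30), POL1 (1.07) and URA7 (1.33). Median differences below 0 were found for heat shock chaperones (-0.52, adjusted p = 0.00062, and adjusted p = 0.27 with an estimated correlation) and oxidative stress defence (-0.86, adjusted p = 0.00020, and adjusted p = 0.16 with an estimated correlation). They were also found for glycolysis and fermentation (-0.44, adjusted p = 0.00029, and adjusted p = 0.27 with an estimated correlation), the tricarboxylic acid cycle (-0.54, adjusted p = 0.0056, and adjusted p = 0.19 with an estimated correlation) and nitrogen-repressed genes (-0.53, adjusted p = 0.028, and adjusted p = 0.24 with an estimated correlation). Examples were HSP30 (-4.78), TSA2 (-2.81), PYK2 (-3.79), CIT1 (-0.91) and MEP2 (-2.31). Oxidative phosphorylation was lower as well (-0.23, adjusted p = 0.010, and adjusted p = 0.43 with an estimated correlation), but its median difference was 0.04 with arrays scaled to the same spread and 0.14 on repeat arrays alone. The numbers of genes higher and lower were 24 and 1 of 32 (translation factors), 22 and 1 of 28 (G1 and S), 15 and 2 of 23 (G2 and M), 9 and 0 of 11 (polymerases) and 10 and 2 of 13 (pyrimidine). For the lists below 0 they were 2 and 20 of 28 (heat shock), 0 and 16 of 23 (oxidative stress), 0 and 15 of 20 (glycolysis), 0 and 10 of 12 (tricarboxylic acid), 5 and 14 of 30 (nitrogen) and 1 and 14 of 35 (oxidative phosphorylation). Besides the estimated correlation, alternatives lost the calls of pyrimidine synthesis (7), the tricarboxylic acid cycle (6), the polymerases (5), oxidative phosphorylation (5), nitrogen-repressed genes (4) and G2 and M phase (2), again with their number in brackets. Not counted there, oxidative phosphorylation also lost its call where its median reversed. This was with arrays scaled and on repeat arrays alone (camera, adjusted p = 0.61 and 0.44). Adjusted over the list alone, 1 oxidative stress gene was higher and 16 were lower, and the other counts stayed the same.

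The phosphate regulon and the mating pheromone response, which fell in both comparisons, did not pass as lists in the difference. Their median differences were -0.17 (adjusted p = 0.30) and -0.02 (adjusted p = 0.57), and 1.59 and 0.34 with arrays scaled to the same spread, where both passed with the sign reversed (adjusted p = 0.0014 and 0.018). Within them PHM8 (-3.0) and FUS1 (-2.56) were lower in the mutator and STE2 (1.01) lower in the non-mutator. The other lists that did not pass were, from the smallest p, cell wall, proteasome, mismatch repair, histones, copper and zinc homeostasis, auxotrophic marker genes, glucose-repressed carbon metabolism and base excision repair (adjusted p = 0.051 to 0.19). Next were purine and one-carbon metabolism, sulfur and methionine metabolism, iron regulon, hexose transport, thiamine and pyridoxine synthesis, phospholipid synthesis and telomere maintenance and silencing (adjusted p = 0.19 to 0.38). They were followed by flocculins and cell-surface adhesion, meiosis and sporulation, translesion synthesis and postreplication repair, multidrug resistance, homologous recombination, amino acid biosynthesis and ergosterol synthesis (adjusted p = 0.47 to 0.59), and by haploid-specific genes, daughter-cell separation, dNTP synthesis and DNA damage checkpoint and nucleotide excision repair (adjusted p = 0.60 to 0.97). Some of these lists passed in alternatives, with their number in brackets: cell wall (9), auxotrophic marker genes (4), iron regulon (3), ergosterol synthesis (1), glucose-repressed carbon metabolism (1), hexose transport (1), proteasome (1) and purine and one-carbon metabolism (1). Hexose transport passed with its median difference reversed to -0.18 with the RNA number as a random block, -0.16 with the round as one and -0.0054 with array weights (cameraPR, adjusted p = 0.034, 0.038 and 0.012). In the mutator, the non-mutator and the difference, the median, mean and test of each list that passed had the same sign. They differed in sign in lists that did not pass: nucleotide excision repair, purine and one-carbon metabolism, iron regulon, phospholipid synthesis and multidrug resistance in the mutator, mismatch repair, translation factors, meiosis and sporulation, heat shock chaperones, nitrogen catabolite repressed, telomere maintenance and silencing and auxotrophic marker genes in the non-mutator, and nucleotide excision repair, hexose transport, haploid-specific genes and meiosis and sporulation in the difference. Adjusted over the list alone, counts of the lists that did not pass in the difference moved by at most 6.

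Genes called in both comparisons were then counted. The a-factor genes MFA1 and MFA2, BAR1, STE2, AGA2 and the pheromone desensitisation gene SST2 (-1.66 and -1.82) fell at least 2-fold in both, STE2 in the mutator only as the mean of both rounds. So did the phosphate genes PHO8 (-1.21 and -1.30), PHO84 (-2.38 and -1.35), PHO89 (-1.60 and -1.95), SPL2, VTC3, PHO11 and PHO12, the genes ARR3 and NDJ1, YNL089C and 1 probe with no gene name. These 17 compare with 3.71 for independent calls. At that size 8 probes fell in the mutator and rose in the non-mutator (1.64 for independent calls), 0 did the reverse (2.44), and 2 rose in both (1.07), YPS5 and 1 probe with no gene name. VTC3, ARR3 and NDJ1 were chosen after their values were seen. At any size, 381 probes fell in both (287 for independent calls, Fisher's exact test, two-sided, adjusted p = 3.2e-13) and 194 rose in both (260, adjusted p = 3.8e-08). In opposite directions, 418 fell in the mutator and rose in the non-mutator (264, adjusted p = 4.0e-35), HIS3, AMS1 and GTT1 among them. A further 223 rose in the mutator and fell in the non-mutator (283, adjusted p = 1.4e-06), such as OAC1 and LEU1. These tests run across probes, which are not independent replicates. Both sets of calls also use the same residual spread per probe, so a probe with a small spread passes more easily in both. The counts for independent calls leave this out. The p-values therefore do not show by themselves that the changes are related. The 575 probes called the same way became 243, 127 and 125 without non-mutator replicate 2, 3 and 4. Left out in the same order, the 418 became 190, 137 and 138 and the 223 became 84, 40 and 48. Calls in opposite directions outnumbered calls the same way at any size, but not at a size of at least 2-fold. Nor did they with array weights or the round as a random block. The shortfall of shared increases depended on processing. With arrays scaled to the same spread 482 probes rose in both (429 for independent calls, adjusted p = 0.0014), and with array weights 563 (538, adjusted p = 0.13). Across all 6866 probes the mean changes were nearly uncorrelated (Pearson's r = 0.0045, Spearman's rho = 0.027, covariance 0.0010), and r between single arrays of the sets ranged from -0.032 to 0.057.

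**Figure D3:**
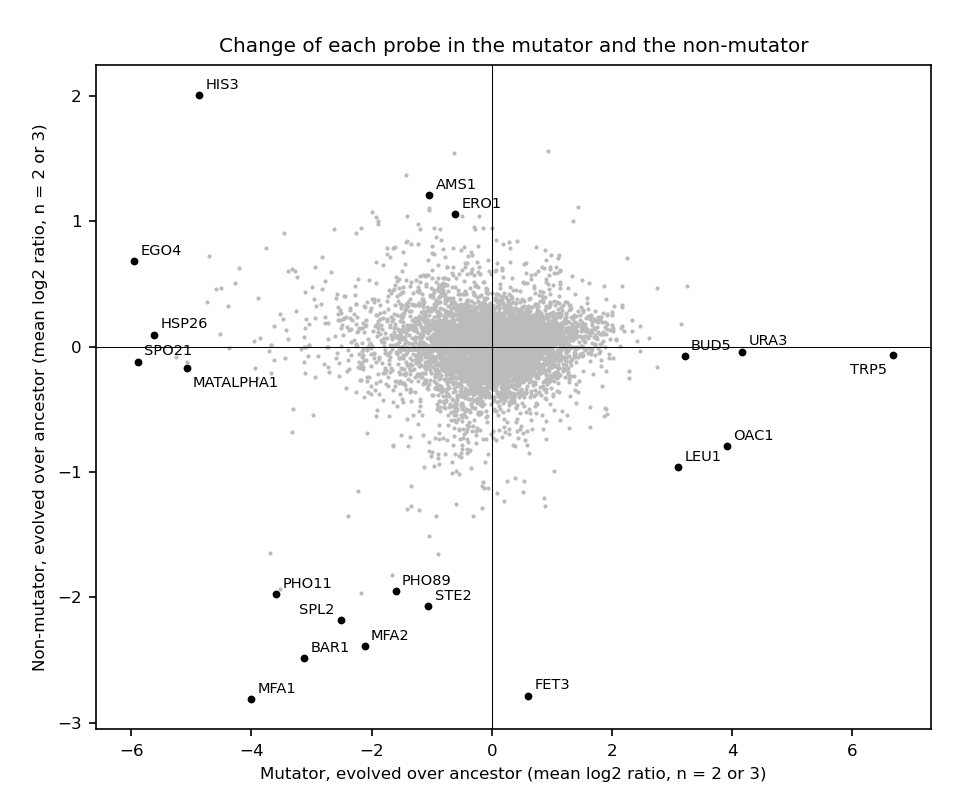
Mean log2 ratio (evolved over ancestor) of each probe in the mutator, on the horizontal axis, and in the non-mutator, on the vertical axis; labelled points are named genes. MFA1, BAR1, MFA2, SPL2 and PHO11 lie low on both axes, HIS3 lies at -4.87 and 2.01, and across 6866 probes r is 0.0045.

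Chromosomes were tested in the same way as lists, using chromosome names from the reference table. The 19 mitochondrially encoded genes were higher in the mutator (median 0.73, adjusted p = 0.015, and adjusted p = 0.94 with an estimated correlation) and in the difference (median 0.78, adjusted p = 0.013, and adjusted p = 0.95 with an estimated correlation). The call in the mutator was also lost with first-round arrays only, the RNA number or the round as a random block, robust eBayes or array weights. All of these but the first-round fit used cameraPR, so the setting and the change of test cannot be told apart. That in the difference was lost with first-round arrays only or arrays scaled to the same spread. Medians of the nuclear chromosomes lay between -0.23 and 0.06 in the mutator and between -0.02 and 0.02 in the non-mutator, and none of them passed in any of the 3 comparisons.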

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

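The tests of explanations for the 3 patterns were chosen only after the results were seen, whereas the counts over other splits of the replicates were planned. Of 55 sets of values over the 6 mutator arrays, 3 had 1 array far from the others by Dixon's test, and chance alone gives about 1 in 20. URA3 was at 1.44 on the repeat array of replicate 1, against 4.30 to 5.69 on the other arrays. RFC3 was at 0.069 on the repeat array of replicate 3, against 0.28 to 0.40. The median of the cell wall list was -0.30 on the repeat array of replicate 1, against -0.49 to -0.43.

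Changes that differed between mutator and non-mutator, by limma's test of the difference, covered 4390 probes. The tested genes with the largest positive differences were TRP5 (6.75), OAC1 (4.70), URA3 (4.21), LEU1 (4.07), FET3 (3.39), BUD5 (3.28), PUF3 (2.97), HEM3 (2.91), BRN1 (2.76) and RSA4 (2.54). Those with the largest negative differences were HIS3 (-6.88), EGO4 (-6.64), SPO21 (-5.77), HSP26 (-5.72), GPH1 (-5.43), RGI1 (-5.09), YRO2 (-5.05), RTC2 (-4.97), HMLALPHA1 (-4.96) and MATALPHA1 (-4.90), where those of EGO4 and HMLALPHA1 are lower bounds in size because floor ratios were set to missing. Median differences were positive for ribosome biogenesis (1.33), pyrimidine synthesis (0.84), G1 and S phase (0.65), G2 and M phase (0.61), replicative polymerases (0.59), translation factors (0.42) and cytosolic ribosomal proteins (0.39). They were negative for general stress (-2.93), oxidative stress (-0.86), the tricarboxylic acid cycle (-0.54), nitrogen-repressed genes (-0.53), heat shock chaperones (-0.52) and glycolysis (-0.44). The median difference of oxidative phosphorylation was -0.23, but 0.041 with arrays scaled to the same median absolute deviation. Mitochondrially encoded genes differed by a median of 0.78, a call lost with arrays scaled or first-round arrays only. With an estimated correlation none of these lists passed, nor did the mitochondrial genes (adjusted p = 0.95).

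The 10 splits of the 6 replicates into 3 and 3 are too few for a share under 0.05. The real split gave 4390 probes, and the highest other split 0, so 1 split of 10 gave as many. For lists the real split gave 14 and the highest other 15, with 2 splits giving as many. For chromosomes the real split gave 1 and the highest other 2, with 5 splits giving as many. Each other split sets 2 replicates of one group and 1 of the other against the reverse, so it keeps part of the real difference. The mixing also puts the difference between mutator and non-mutator into the spread within each side, which lowers the probe count. The 0 probes of other splits therefore do not measure what chance gives. Why list and chromosome counts were as large in other splits was not tested.

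Marker and mating-type genes had extreme ratios in the mutator, and 8 such loci were compared with their neighbours. The largest size of the median of the 8 flanking genes was 0.65, at MET17, whose own ratio was -2.10. That argues against a copy change of the surrounding segment at these loci. A copy change of the central gene alone or of a few genes remains open at each of them, MATALPHA1 included. The median of the flanking genes cannot show such a change. The smallest size of the difference between mutator and non-mutator over these loci was 2.27, which argues against a dye effect shared by both array sets. Different marker genotypes of the strains compared remain open, as 6 of 10 marker genes passed a 4-fold change and the labels give no genotypes. Changes acquired during evolution remain open too and were not tested.

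General stress genes fell and ribosome biogenesis genes rose in the mutator. The median nearer to 0 of the hybridisation rounds was -2.60 for general stress and 1.41 for ribosome biogenesis, which argues against either change coming from a single round. The non-mutator median of the stress list was 0.0297, with 31 of 32 genes past limma's test of the difference and the list past camera's (adjusted p = 3.1e-15, and adjusted p = 0.16 with an estimated correlation), which argues against a dye effect shared by both array sets. The growth state of the cultures at harvest could have contributed and remains open: array medians of the stress list were -3.26 ± 0.14 (SD, n = 3) in the first round and -2.60 ± 0.17 (SD, n = 3) in the repeat, 0.66 apart, and the labels do not say whether the rounds came from separate cultures. A heritable change of the evolved mutator also remains open and was not tested.

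Phosphate and pheromone genes fell in both evolved strains. Of 47 tested members of these lists, 33 fell in the mutator, 27 in the non-mutator and 24 in both, against 19.0 for independent calls (Fisher's exact test across genes, two-sided, p = 0.0028). Both sets of calls use the same residual spread per probe, which the count for independent calls leaves out. Of those 24, 11 differed between mutator and non-mutator, 8 being lower in the mutator and 3 in the non-mutator. A dye effect of the same size on all arrays leaves those 11 differences unexplained but is open for the rest. As the array sets differ in spread, a dye effect of a different size in each set is open for all 24. Parallel change during evolution and a dye effect therefore cannot be told apart for these genes, since no array had its dyes swapped.

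A signal also appeared in a gene outside the tests. The ratio of ERR1 was 4.29 to 4.75 on the non-mutator arrays, while it stood at the floor of 0.01 on 5 of 6 mutator arrays. ERR1 has near-identical copies, so which copy gave the signal is uncertain.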

How the results depend on the processing

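The fits with the hybridisation round as a random block, with floor ratios kept, with ratios of no more than 1 decimal set to missing and with reference-table probes only were tests chosen only after the data were seen, and the others were planned. The mutator count of 5154 probes ranged from 3605 to 5246 over the other alternatives, with 1241 at a log2 size of at least 1 and 4823 to 5022 on leaving out a replicate. The difference count of 4390 ranged from 3437 to 4608, with 2675 with the round as a random block, 1328 at a log2 size of at least 1 and 3773 to 4545 on leaving out a replicate.

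The non-mutator count of 1457 probes depended most on processing. It became 3455 with arrays scaled to the same median absolute deviation, 2994 with array weights and 2479 with each group fitted alone. It became 298 with the 6 mutator arrays as replicates, 316 with the RNA number as a random block, 868 and 741 with first-round or repeat mutator arrays only, and 83 with the round as a random block, where the non-mutator arrays form 1 block. At an adjusted p under 0.01 it was 504, and at a log2 size of at least 1 49. Without non-mutator replicate 2, 3 and 4 it was 603, 347 and 351, within a range of 347 to 1875 on leaving out any replicate. Leaving out a replicate leaves fewer arrays to the fit. Except where each group was fitted alone, the fit pools a single residual spread per probe over both groups. Calls in the non-mutator therefore also depend on the spread of the mutator arrays. How far this accounts for the other alternatives was not tested.

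The 575 probes called the same way in both comparisons (194 higher) became 996 (482 higher) with arrays scaled, 1159 (563 higher) with array weights and 545 (239 higher) without centring. The count was 117 with 6 arrays as replicates, 129 with the RNA number as a block, 332 with first-round and 260 with repeat mutator arrays only, 35 with the round as a block and 165 at an adjusted p under 0.01. Without non-mutator replicate 2, 3 and 4 it was 243, 127 and 125, within 125 to 723 on leaving out any replicate. The overlap test was repeated in every fit of both groups together, a test chosen only after the data were seen. In each of these fits both sets of calls use the same residual spread per probe, which the counts for independent calls leave out. Shared increases were fewer than for independent calls except with arrays scaled (482 against 429, adjusted p = 0.0014) and with array weights (563 against 538, adjusted p = 0.13), and for the other 3 directions the count stayed on the same side of it. The correlation across genes stayed between -0.021 and 0.016.

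With an estimated correlation 0 of 19 lists passed in the mutator, 0 of 11 in the non-mutator and 0 of 14 in the difference; over the other alternatives the counts were 16 to 25, 9 to 12 and 11 to 17, and on leaving out a replicate 19 to 21, 10 to 12 and 14 to 15. Of the lists that differed, 10 of 14 were higher with arrays scaled, against 7 of 14. The chromosome count in the mutator was 0 with the RNA number or the round as a block, first-round arrays only, robust eBayes, array weights or an estimated correlation, and 1 otherwise. The random blocks, robust eBayes and array weights also changed the test to cameraPR. In the difference it was 0 with arrays scaled, first-round arrays only or an estimated correlation. In the non-mutator it was 0 to 1 on leaving out a replicate, the 1 without non-mutator replicate 2.

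Directions reversed in these results, and the cause was not tested. With arrays scaled, the median difference became 0.041 for oxidative phosphorylation, 0.34 for mating pheromone response (adjusted p = 0.018, over all alternatives 0.018 to 0.74) and 1.59 for the phosphate regulon (adjusted p = 0.0014, over all alternatives 0.0014 to 0.43). On repeat arrays only, oxidative phosphorylation became 0.077 in the mutator and 0.14 in the difference, and the iron regulon 0.48 in the mutator (adjusted p = 0.013). The median difference of hexose transport became -0.18 with the RNA number as a block, -0.0054 with array weights and -0.16 with the round as a block (cameraPR, adjusted p = 0.034, 0.012 and 0.038). All alternatives were followed for 254 results on named genes and 126 on lists. Reversed results left aside, calls were lost 2, 107 and 12 times for genes and 34, 22 and 43 times for lists in the mutator, the non-mutator and the difference. Of genes, 1 alternative each lost PMS1 (repeat arrays only) and MSH3 (the round as a block) in the mutator. In the difference PMS1 was lost 7 times, RFC4 2 times and CIT1, CDC20 and MLH3 once each. In the non-mutator 27 genes lost their call, all with the round as a block, and most often RFC5 (10), EBP2 (7), RPT1 (7), NOG1, PRE5, RPN3, RRP1 and ZAP1 (6 each). Gene calls were gained 1, 15 and 8 times, all in mismatch repair genes. Only these were followed whether called or not, so no other gene could gain a call. Every list lost its call with an estimated correlation. Lists lost in other alternatives were mismatch repair (4), proteasome (4), pyrimidine synthesis (4), oxidative phosphorylation (2) and tricarboxylic acid cycle (1) in the mutator, haploid-specific genes (6) and copper and zinc homeostasis (5) in the non-mutator and pyrimidine synthesis (7), tricarboxylic acid cycle (6), oxidative phosphorylation (5), replicative DNA polymerases (5), nitrogen catabolite repressed (4) and G2 and M phase cell cycle (2) in the difference. Not counted there, oxidative phosphorylation also lost its call where its median reversed. This was on repeat arrays only in the mutator and the difference, and with arrays scaled in the difference. List calls were gained with the sign kept 43, 4 and 21 times, most often by auxotrophic marker genes (9), histones (8), thiamine and pyridoxine synthesis (7), glucose-repressed carbon metabolism (6), hexose transport (6) and amino acid biosynthesis (3) in the mutator and cell wall (9), auxotrophic marker genes (4) and iron regulon (3) in the difference.

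A replicate block over the numbers 2 and 3 gave 3437 of 6733 probes that differed, and the same 4 replicates without it 3890; deviations of same-number replicates correlated at -0.020 and 0.016 across probes, and the labels give the groups no shared material beyond the number. Testing each probe on its own changed nothing, as no gene had more than 1 probe, and each group fitted alone gives no test of the difference. Signal over background is not given, so its limit on the ratios is unknown.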

Other observations

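The 4 gene lists in this part, their members and all of their tests (limma's camera) were chosen only after the data were seen, from genes such as OAC1, LEU1, ERO1, DER1 and MFA1 that had stood out, so their p-values are not independent evidence. These lists were not part of the adjustment over the lists reported under Results. Their adjusted p have the pattern of an adjustment over the added lists alone, which is a milder correction. A pass here, with the preset or an estimated correlation, therefore cannot be set beside the counts of passing lists given above. Of targets of the leucine regulator Leu3, 6 rose and 2 fell of 8 in the mutator (median 1.47, adjusted p = 0.015, and adjusted p = 0.085 with an estimated correlation). The same targets gave 0 rose and 6 fell of 8 in the non-mutator (median -0.50, adjusted p = 1.6e-06, and adjusted p = 0.0076 with an estimated correlation), and they differed between mutator and non-mutator (median difference 1.51, adjusted p = 0.00029, and adjusted p = 0.027 with an estimated correlation). ILV5 was at 1.88 and ILV2 at 0.53 in the mutator.

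Of unfolded protein response genes, 12 rose and 2 fell of 15 in the non-mutator (median 0.67, adjusted p = 2.5e-07, and adjusted p = 0.0075 with an estimated correlation), for example SIL1 (0.95), LHS1 (0.85), JEM1 (0.84), EUG1 (0.74) and KAR2 (0.37). As a list they did not pass in the mutator, where the counts were 2 rose and 10 fell of 15 (median -0.22, adjusted p = 0.0501, and adjusted p = 0.10 with an estimated correlation), and they differed between mutator and non-mutator (median difference -1.07, adjusted p = 0.00029, and adjusted p = 0.027 with an estimated correlation). HAC1, which encodes the regulator of the response, was at -1.26 in the mutator and -0.10 in the non-mutator, where it did not pass.

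Of a-specific genes, 0 rose and 7 fell of 7 in the mutator (median -2.11, adjusted p = 0.00066, and adjusted p = 0.057 with an estimated correlation), and 0 rose and 6 fell of 7 in the non-mutator (median -2.07, adjusted p = 1.5e-09, and adjusted p = 0.0075 with an estimated correlation). They did not pass the test of the difference (median difference -0.64, adjusted p = 0.69, and adjusted p = 0.70 with an estimated correlation). Of alpha-specific genes only 4 could be tested, too few for a list test, with 2 lower in the mutator (median -0.35) and 2 lower in the non-mutator (median -0.33).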
